A study of Manihot esculenta with 3 samples.

How the data were processed

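Messenger RNA was measured in leaves of the cassava (Manihot esculenta) cultivar TME 7, in 3 replicate libraries that form 1 group. Per the labels' protocols, total RNA came from a fully expanded leaf, the 3rd or the 4th, of plants 7.5 weeks old, was freed of genomic DNA, selected for polyadenylated transcripts, and sequenced as paired-end reads from a pool of the libraries. The labels do not say which leaf was taken for which library, nor whether each library came from a separate plant, so the spread between replicates may be partly or wholly technical.

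The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to a common number of mapped fragments per library), with a column per library, per the file headers. The submitters' processing notes list TopHat2 2.0.11, a spliced aligner, and Cufflinks 2.2.1, which estimates transcript abundance. The genome build, the settings and any further scaling between libraries are not given in the sources used here. Gene identifiers carry the annotation suffix v6.1. No per-sample column was left unused (0 columns). Cufflinks-type FPKM values are not counts: they divide each gene's fragments by its usable length and by a library total, an exact 0 can be a failed estimate, and the fragments behind a value are not listed. No count model was therefore used, and no counting intervals or detection floors are given. The absolute depth of the libraries is unknown. Their relative depth was estimated from genes whose mean over a pair of libraries was below 0.6 FPKM, because the ratio of such values is a ratio of small whole numbers (1 to 4) times the ratio of the values of a single fragment. The offset that placed most ratios within 0.01 log2 units of such numbers was taken.

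The identifiers were looked up in a RefSeq gene table of another assembly (M.esculenta_v8), in its identifier, locus tag, symbol, synonym and accession columns. Of 33033 identifiers 0 matched, and the deposited table does not pair identifiers with names. The 31 gene lists fixed before the data were examined (photosynthesis, cyanogenic glucosides, DNA methylation, small RNAs, cell type markers and others) could therefore not be filled, and no gene function is reported here. The planned analyses of level, replicate deviation and spread of those lists, which were to be read against random lists, were void.

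Levels were summarised as the number of genes at or above 1, 10, 100 and 1000 FPKM and as the share of summed FPKM in the highest genes. Agreement was measured as Pearson's r and Spearman's rho across genes on log2(FPKM + 1) for genes with a mean of at least 1 FPKM. Genes are not independent replicates, so no p-value was attached. Spread was the SD over the 3 libraries of log2(FPKM + 1), a scale that understates differences of low genes. The deviation of a library was its log2(FPKM + 1) minus the mean of the other 2 libraries. With 1 group there was no test between groups. The exact sign-flip test planned for a difference between 2 genes cannot give a p below 0.25 with 3 libraries, and the genes compared were chosen on their means, so no p is reported from it. Under the rule fixed before the data were examined for identifiers without names, the 2 genes with the highest mean and the 2 with the largest log2 SD among genes of mean 10 FPKM or more are given by identifier. A further 3 genes were chosen after their values were seen and are introduced as such.

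Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, thresholds of 0.5 and 0.1 FPKM, upper quartile and median-of-ratios scaling, leaving out the highest gene, and leaving out each replicate. A pair of alternatives was added after seeing the data: leaving out genes that held a value of 100 FPKM or more identical to that of another gene of the library, or 2 to 5 times such a value within a relative tolerance of 1e-05, and keeping only genes above 0 in all 3 libraries. The statistics were tested on simulated libraries of 33033 genes. There, 100% of genes changed 4-fold in 1 library and 58% of genes changed 2-fold had a log2 range over 1, against 0% of unchanged genes of 10 FPKM or more. Unchanged genes were simulated with a small, even spread between libraries and without failed estimates. The 0% follows from that setting and is not a rate of false calls in the real libraries. The log2 depth ratio was recovered within 0.0085. Each simulated gene had whole fragments and the same length in all libraries, so the steps were exact. This recovery is therefore not the error of the real depth ratios. All 56 planted short genes at 100 FPKM or more were found by shared values or multiples of them, along with 26 other genes. The planted genes were given a few exactly equal lengths, which makes shared values certain. Their recovery is therefore no measure of how many real short genes are found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.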

Results

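The transcriptome of the cassava leaf was profiled as the expression part of a methylome study. Cassava is a tropical root crop, and TME 7 is the cultivar from which leaves were taken. The 3 libraries were replicates of 1 group, with no treated or contrasting sample, so the design addressed which genes the leaf expressed, at what level, and how closely the replicates matched. The table listed 33033 genes in FPKM, of which 31895 carried the number of 1 of 18 chromosomes in their identifier and 1138 carried the letter S in its place. Summed FPKM was 915718 in replicate 1, 915236 in replicate 2 and 952243 in replicate 3.

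Depth was unequal between the libraries. Among low genes, the ratios of values between libraries fell on discrete steps, as they do when few whole fragments are counted. The value of a single fragment in replicate 3 was 1.57 times that in replicate 1 and 1.54 times that in replicate 2, whereas replicates 1 and 2 differed by a factor of 1.02. Median-of-ratios factors of the deposited values were 1.001, 0.9998 and 1.003 for replicates 1, 2 and 3, so the libraries already lay on a common scale, and a scaling between libraries by the authors cannot be excluded. Whichever scaling was used, a low gene at equal FPKM rested on 0.635 times as many fragments in replicate 3 as in replicate 1. Between 37.8% and 56.8% of 2635 to 2881 low genes per pair of libraries lay at these steps, against 1.71% to 2.86% at shifted positions. Replicate 3 also listed the most genes at 0, with 7131, against 6636 in replicate 1 and 6514 in replicate 2.

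**Figure D1:**
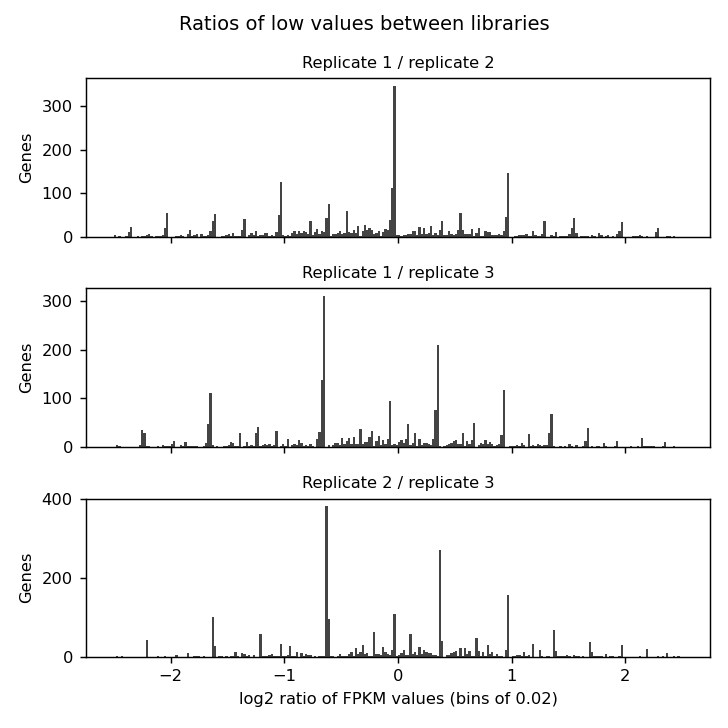
Histograms of the log2 ratio of FPKM values between each pair of libraries (x axis, log2 units; y axis, number of genes) for genes above 0 in both and with a mean below 0.6 FPKM. The tallest peaks of the lower panels stand near -0.655 (replicate 1 over replicate 3) and -0.62 (replicate 2 over replicate 3), and the tallest peak of the upper panel stands near -0.03.

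Most listed genes were expressed in the leaf at 1 FPKM or more. The number was 21465 ± 149 genes per library (SD, n = 3), or 65.0% ± 0.45 of those listed. In all 3 libraries 20382 genes reached that level, which was 90.2% of the 22585 genes that reached it in any library. At 10 FPKM or more there were 11687 ± 42 genes, at 100 FPKM or more 1279 ± 42 genes, and at 1000 FPKM or more 101 ± 3.0 genes (SD, n = 3). At the other end, 5374 genes, 16.3% of those listed, were at 0 in every library. The median gene stood at 4.27 ± 0.12 FPKM (SD, n = 3). A further 2745 genes were listed at 0 in some but not all libraries, and 127 of these had a mean of 10 FPKM or more.

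**Figure D2:**
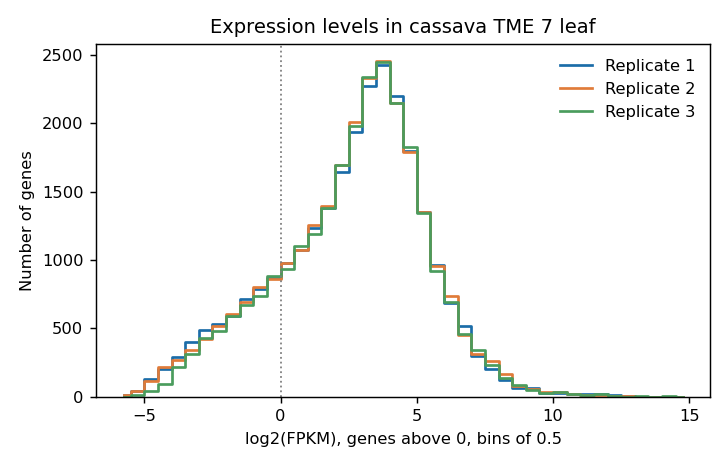
Number of genes (y axis) by log2(FPKM) in bins of 0.5 (x axis) for genes above 0 in each of the 3 libraries; the dotted line marks 1 FPKM. The 3 curves rise to a single peak in the same bin, centred on 3.75, with a long shoulder of genes below 1 FPKM.

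A small number of genes held much of the signal. The 10 highest genes of each library held 12.6% ± 1.6 of summed FPKM, the 100 highest 33.2% ± 1.9 and the 1000 highest 59.1% ± 1.1 (SD, n = 3). The gene with the highest mean was Manes.01G011500.v6.1, on chromosome 1 by its identifier, with 25529 ± 1731 FPKM (SD, n = 3). It ranked 1 in every library and alone held 2.75% ± 0.19 of summed FPKM. Manes.05G137400.v6.1, on chromosome 5, came next with 19614 ± 5806 FPKM (SD, n = 3), and its replicate 1 value of 13188 FPKM lay below its values of 24482 and 21172 FPKM in replicates 2 and 3. The difference between these 2 genes averaged 0.43 ± 0.37 on the log2 scale (SD, n = 3). Its direction was set by choosing the genes on their means in these libraries, so it was not tested. Of the 100 highest genes of each library, 85 were common to all 3, and 94 were common to replicates 2 and 3. Of the 1000 highest, 769 were common to all 3.

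The 10-gene share was uneven between libraries: it was 11.5% in replicate 1, 11.9% in replicate 2 and 14.4% in replicate 3. In replicate 3, Manes.06G010900.v6.1 and Manes.13G092200.v6.1 were both listed at exactly 16956.1 FPKM and together held 3.56% of summed FPKM, while both were listed at 0 in replicates 1 and 2. They were the 2 genes with the largest SD among genes of mean 10 FPKM or more. Counting this pair, values of 100 FPKM or more that were identical to that of another gene occurred in 31 genes of replicate 1, 37 of replicate 2 and 28 of replicate 3. Of these, 54.8%, 62.2% and 60.7% were listed at 0 in another library, against 0.166%, 0.313% and 0.0801% of the other genes at 100 FPKM or more. Without the 84 genes that shared such values or lay at whole multiples of them, the 10-gene share was 12.02% ± 0.30 (SD, n = 3).

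The replicates matched closely for most genes, with replicate 1 the farthest from the rest. Across 21663 genes with a mean of at least 1 FPKM, Pearson's r on log2(FPKM + 1) was 0.945 for replicates 2 and 3, 0.930 for replicates 1 and 3 and 0.929 for replicates 1 and 2. Spearman's rho was 0.959, 0.943 and 0.936 for the same pairs. These are correlations across genes, which are not independent replicates. No library was an exact copy of another, since at most 1 gene above 0 had an identical value in both members of a pair. This cannot show whether 2 libraries came from the same RNA. The mean r of the 3 pairs was 0.935 ± 0.009 (SD) over these genes and 0.971 ± 0.014 (SD) when those listed at 0 in any library were left out. Genes at 0 in only some libraries disagree by definition, so leaving them out favours a higher r. The 3 pairs share the same libraries, so these SDs are not over independent values.

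The median SD of log2(FPKM + 1) per gene was 0.19, and 95% of genes lay below 0.65. A log2 range over 1 is more than a 2-fold difference in FPKM + 1 between the highest and lowest library. Low genes need a larger fold difference in FPKM to reach it, so classes of level are not held to the same fold. Such a range was found in 1854 genes, 8.56% of those measured. The share was 13.1% among genes of 1 to 2 FPKM, 6.25% among those of 10 to 50 FPKM and 16.5% among those of 100 to 1000 FPKM. Without replicate 1 the median SD was 0.11 and 504 genes differed by that much between replicates 2 and 3. Without replicate 2 the number was 970, and without replicate 3 it was 1406. A range over 2 libraries cannot exceed the range over 3. The median of SDs over 2 libraries also tends to be lower than that over 3, so 0.11 and 0.19 are not directly comparable.

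Replicate 1 deviated most in each of 7 classes of mean level. Among 11817 genes of mean 10 FPKM or more, its median absolute deviation from the other libraries was 0.25 on the log2 scale, against 0.19 for replicate 2 and 0.12 for replicate 3. Among these, 207 genes were higher and 358 lower in replicate 1 by more than 1 log2 unit. The counts were 179 higher and 106 lower in replicate 2, and 96 higher and 111 lower in replicate 3. A value far out in 1 library also moves the deviations of the other 2 the opposite way. The same gene can therefore enter several of these counts. They also include genes listed at 0 in 1 or 2 libraries, of which there were 127 at this mean level. The labels give no property that separates replicate 1 from the others.

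**Figure D3:**
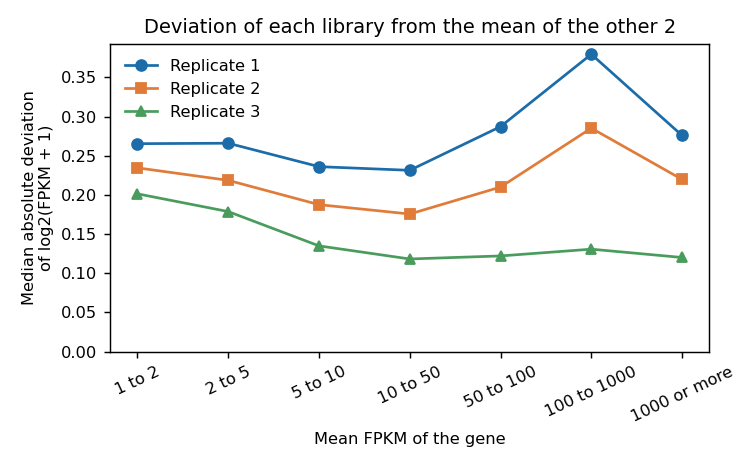
Median absolute deviation of each library from the mean of the other 2, on the log2(FPKM + 1) scale (y axis), by class of mean FPKM (x axis). Replicate 1 lies above replicate 2 and replicate 3 lies lowest in each of the 7 classes, with replicate 1 highest, at 0.38, among genes of 100 to 1000 FPKM.

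A pair of genes chosen after their values were seen had the largest SD among genes of mean 10 FPKM or more that were above 0 in all 3 libraries and shared no value with another gene. Manes.05G089800.v6.1, on chromosome 5, stood at 80.0 FPKM in replicate 1, 1.18 FPKM in replicate 2 and 7.42 FPKM in replicate 3. Manes.15G163100.v6.1, on chromosome 15, stood at 19.1 FPKM in replicate 1 and at 329 and 324 FPKM in replicates 2 and 3, which were 17.24 and 16.96 times the replicate 1 value. For Manes.05G089800.v6.1 all 3 libraries differed, and for Manes.15G163100.v6.1 the contrast sets 1 library against 2. Neither has a replicate check.

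**Figure D4:**
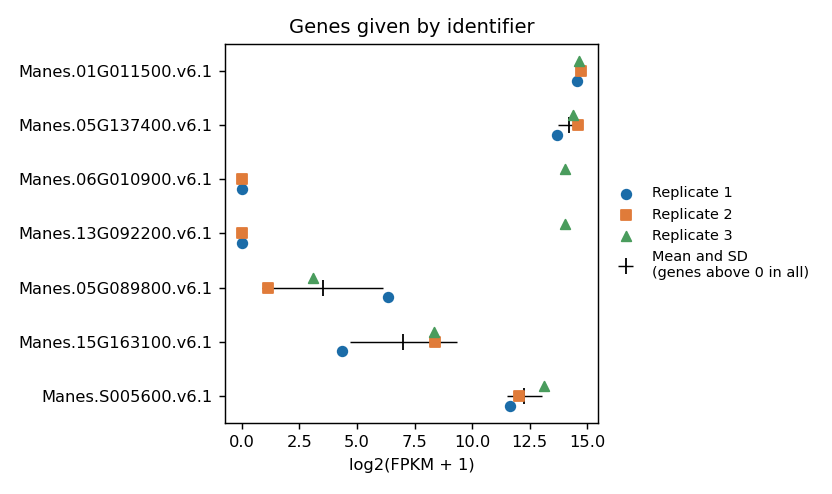
Values of log2(FPKM + 1) (x axis) in the 3 libraries (points) for the genes given by identifier (y axis); black bars show the mean and SD over 3 libraries for genes above 0 in all of them. Manes.06G010900.v6.1 and Manes.13G092200.v6.1 lie at 0 in replicates 1 and 2 and at the same high value in replicate 3, and Manes.15G163100.v6.1 is lowest in replicate 1.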

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

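The number of genes at 1 FPKM or more in every library was 20382, and ran from 20346 to 20863 under the alternatives that kept this threshold. It was 21919 at a threshold of 0.5 FPKM and 24263 at 0.1 FPKM. The larger agreement of replicates 2 and 3 kept its sign under all 5 of its alternatives. Agreement depended on which genes entered. The mean Pearson r was 0.892 with a pseudocount of 0.1, 0.961 over genes above 0 in any library, 0.902 over genes of mean 5 FPKM or more, 0.951 without genes with shared values and 0.971 over genes above 0 in all libraries. The last 2 sets were chosen after seeing the data, and the last leaves out genes that disagree by definition. Mean Spearman rho was 0.958, 0.922 and 0.968 over genes above 0 in any library, of mean 5 FPKM or more, and above 0 in all libraries. Without the highest gene, the shares of summed FPKM in the highest 1, 10 and 1000 genes were 2.36%, 10.7% and 57.9%, by construction. Genes with a log2 range over 1 numbered 1854 in the main setting and 2713 with a pseudocount of 0.1, so this number depended on the pseudocount. There were 2069 among genes above 0 in any library, and 1175 among genes of mean 5 FPKM or more, where fewer genes were tested. Leaving out each replicate gave 504 to 1406 such genes and a median SD of 0.11 to 0.20, both lowest without replicate 1. A range over 2 libraries cannot exceed that over 3, so the fall in the number of genes is partly by construction. The median of SDs over 2 libraries also tends to be lower than that over 3. Upper quartile and median-of-ratios factors differed from 0 by at most 0.010 log2 units and barely tested scaling. The means of Manes.06G010900.v6.1 and Manes.13G092200.v6.1 were 0 without replicate 3, and that of Manes.05G089800.v6.1 was 4.30 without replicate 1 against 29.5 FPKM with it. The alternatives planned for gene lists were not run, because no list could be filled. By the estimate from low values replicate 3 had the fewest fragments, and what this limits among low genes cannot be read from deviations on the log2(FPKM + 1) scale.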

Other observations

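All tests in this part were chosen after the values were seen. Genes with S in place of a chromosome number were less often expressed. At 1 FPKM or more, 44.6% ± 1.1 of the 1138 S genes were detected per library, against 65.7% ± 0.48 of the 31895 genes with a chromosome number (SD, n = 3), and their median mean level was 0.654 against 4.63 FPKM. Of the S genes 33.0% were at 0 in all libraries, against 15.7% of the others. Counted by the mean over libraries, 45.6% of S genes reached 1 FPKM. Random blocks of as many successive genes had shares of 45.1% to 71.8% by the same count, and as low a share with permutation p = 0.0016 (10000 blocks, some overlapping the S genes, one-sided). Between numbered chromosomes, the share by that count ran from 59.5% on chromosome 7 to 69.9% on chromosome 16. Circular shifts of the calls along the gene order gave as wide a spread with permutation p = 0.44 (10000 shifts, one-sided). The shifts keep long stretches of seldom detected genes together, also stretches as long as a chromosome. They therefore cannot tell runs of neighbouring genes from differences between whole chromosomes.

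The most abundant genes may include some that rest on a handful of fragments: 3 of the 10 highest means, but 4 of the 100 highest, belonged to genes with a shared value or a multiple of one. In the 3 libraries, 96 values of 100 FPKM or more were identical to that of another gene, against 4 to 44 when each value was moved at random by up to 1% in 1000 redraws, which argues against coincidence for the set though not for each gene. Reads split evenly between near-identical copies would make the same pairs match again. Of 110 pairs that shared a value, 81 had a value above 0 in another library, and 1.23% of those 81 matched again. A pair with 1 gene at 0 there counted as unmatched, although an exact 0 can be a failed estimate. Up to 8 genes shared 1 value, so the pairs are not independent, and some may share a value by coincidence. The low share therefore does not decide whether reads were split evenly. The remaining pairs, among them Manes.06G010900.v6.1 and Manes.13G092200.v6.1, were above 0 in 1 library only. For them evenly split reads could not be examined at all and also stay open. A further 11 values lay at 2 to 5 times a shared value, against 0 to 4 in the redraws, which is in line with few fragments divided by a very short usable length. Manes.S005600.v6.1, chosen after its values were seen, ranked 10 by mean level, yet its 3175.42 FPKM in replicate 1 was 2 times, and its 4235.06 FPKM in replicate 2 was 3 times, a value that 2 other genes shared there (1587.71 and 1411.69 FPKM), so it may stand for 2 and 3 fragments. In replicate 3 its 8838.87 FPKM was 3 times 2946.29 FPKM, which 1 other gene held and which was therefore not a shared value. These steps were in replicate 3 at 1.86 and 2.09 times those in replicates 1 and 2, against 1.57 and 1.54 for low genes, and gene lengths, which could decide the question, were not used here.

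Replicate 1 stood apart from the other libraries. Fewer fragments in replicate 1 are argued against, since the log2 value of a single fragment was -0.655 relative to replicate 3, the shallowest library and the one that deviated least. A single scaling factor leaves the ranks within a library as they are, and is argued against because the ranks also differed. Spearman's rho of replicates 2 and 3 exceeded the higher rho with replicate 1 by 0.0154 (95% bootstrap interval over genes 0.0117 to 0.0193). The interval treats genes as independent, which they are not, and the closest pair was picked on these same values. It does not say whether a library would stand apart in further replicates. Without genes listed at 0 or with shared values, the median absolute deviation of replicate 1 was 0.244, against 0.185 and 0.118 for replicates 2 and 3. Length and GC bias, RNA quality, the leaf position and the plant stay open, as the labels give none of them per library, and no biological explanation was tested.

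Neighbouring genes resembled each other. Identifier order was taken as the order along the chromosome, and the S genes, which carry no chromosome number, were included as a block of their own. The rank correlation of mean level between next genes was 0.121 over 33014 pairs. It lay above all 1000 shuffles within chromosomes and that block, the highest of which was 0.029 (permutation p = 0.001, the smallest they can give). The deviations of replicate 1 were also correlated between next genes, with 0.070 over 14984 pairs against at most 0.026 in 1000 shuffles. Those of replicates 2 and 3 gave 0.061 and 0.067. The deviations of a gene come from the same values and cancel when added, so these correlations are not independent of that of replicate 1. The correlation of level was 0.074, 0.060 and 0.046 for genes 2, 3 and 5 places apart, so it was not confined to next genes. At 10 and 20 places it was 0.025 and 0.012, below the highest shuffle of next genes. Shuffles were run for next genes only. The replicate 1 deviation gave 0.020 at 2 places and 0.0039 at 10, both below the highest shuffle of its next genes. For the deviations, a candidate explanation is that adjacent copies of a gene share reads or respond alike, and these cannot be told apart without sequences of the genes. Both correlations are across genes and small in size.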
